A study of Oryza sativa with 6 samples.

How the data were processed

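The series holds 6 Agilent arrays of 2 colours with 22575 spots each, of which 21495 are rice probes, 918 positive control spots and 162 negative control spots. The labels gave each array's condition, replicate number and the line in each dye. Labelled RNA was made by linear amplification, per the labels' protocols. Spot intensity values (mean signal and local background median in Cy3 and Cy5) were quantified with Agilent Feature Extraction version 7.1 or 8.1, per the file headers. Headers name version 7.1 for replicates 1 and 2 of both conditions and 8.1 for replicate 3 of both, while the submitters' processing notes give 8.1 for P-deficient replicate 2. The deposited log10 ratios of processed Cy5 over Cy3 signals were background-subtracted and dye-normalized by that software (linear, then lowess), per the file headers. The deposited table of the whole series equals these log10 ratios, with the sign turned on the 3 arrays with 6-4 in Cy3, for 22575 of 22575 spots on every array within 0.005, with column medians between -0.0042 and 0.0048. Its scale, direction and centring are therefore known, and it was used as an alternative.

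Background was corrected with limma's normexp at an offset of 50 on mean and background signals, and Cy5 over Cy3 was normalized by loess within each array, with control spots and 569 spots flagged as outliers at weight 0. Probes were kept when well above background on all 3 arrays of at least 1 of the 4 groups of line and condition, which left 20531. Of the rice probes 8561 had a descriptive name, and 8183 of the kept ones did. No probe accession was found in the reference gene table (0 matches), so the names of the array design were kept, no chromosome positions are given, and the planned test of the position of line differences is not run here. Spots well above background were 89.8% to 95.5% of rice probes in Cy3 and 95% to 99.5% in Cy5, with 1 to 4 saturated spots in Cy3 and 32 to 68 in Cy5.

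Line effects came from 1 limma fit (lmFit and eBayes) of log2 6-4 over Nipponbare on all 6 arrays, with a coefficient for each condition and 1 for the dye. It gave the mean of both conditions, each condition, and their difference, over 20528 probes, since 3 had a coefficient that could not be estimated. The response to P deficiency as the mean of both lines was fitted on the mean log2 intensity of both channels after Aquantile normalization between arrays. The response within each line was fitted on the 12 single channels with lmscFit, a dye term and an intraspot correlation of 0.793 estimated from 2000 probes, without 477 probes that had flagged spots. Adjusted p is Benjamini-Hochberg over the probes tested, with a threshold of 0.05. Arrays of P-deficient and control roots are separate, so the response to P is a comparison between arrays while the line effect is within them.

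The 33 gene lists were matched by words in the probe descriptions and tested when at least 5 probes were measured, which left 30. The mycorrhiza and strigolactone list had 0 probes, the phosphate sensing list 2 and the suberin and endodermis list 1 (log2 -0.01 in the mean line effect). Search words were corrected after the probe descriptions had been read and before any fit. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. With an estimated correlation 0 lists passed in any of the 5 comparisons where it was used; at an unadjusted p under 0.05 the counts were 2, 1, 0, 0 and 3 in the mean line effect, under control, under P deficiency, for their difference and in the mean response. Fry, which asks whether a list's probes move one way on balance and does not compare them with other genes, called 1 list in the mean line effect, 2 under control and 4 in the mean response.

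Named genes followed a rule fixed before the data were examined, as were the groups, the designs, the lists and most alternatives. Among described probes past the threshold that went the same way on every array, or did not overlap between conditions, the 10 largest in each direction were taken. Up to 4 probes with the smallest p were added from each called list and from the lists of phosphate sensing and phosphate transport.

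Replicate numbers are shared by the conditions in the labels. Levels of same-numbered arrays deviated together from their condition means, with correlations over probes of 0.382, 0.299 and 0.63 for replicates 1, 2 and 3, each above 0.1, so blocked values stand beside the responses to P. Of differently numbered arrays, control 2 with P-deficient 1 (0.267) and control 1 with P-deficient 2 (0.107) passed that limit too. The first principal component of levels (37.9% of variance) separated the arrays read with version 8.1 from the rest, and the second (33.5%) the conditions. Line ratios of same-numbered arrays deviated against each other (-0.588, -0.747 and -0.366). These arrays hold the lines in opposite dyes. Every pair of arrays with opposite dye orders deviated so (-0.747 to -0.133), and every pair with the same order deviated together (0.326 to 0.679). The sign follows the dye order and cannot tell whether the numbers pair the ratios, so the block stayed an alternative for line effects. Calls with and without the block had been seen in the same early run as these correlations, and the choice rests on the fixed limit of 0.1. The arrays read with version 8.1 hold 1 array of each condition, too few for a fit of their own.

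Alternatives were another or no background correction, the processed signals of the scanner software, other filters and normalizations, no dye term, flagged spots kept, the replicate block, the software version as a batch, and leaving out each array. Tests on the 6844 brightest probes alone, on the arrays of version 7.1, on replicates 1 and 3, and lists with the batch were added after the data had been seen. Each fit was tested on simulated arrays with the real residual spread and 200 changed probes of 20531. At a true log2 change of 1, 90% were called for the mean line effect, 74% for the line effect under control, 58% for the mean response and 48% for the response in Nipponbare, and 4 to 9 of 20331 unchanged probes were called. The simulation has no dye or scanner effect and draws ratios and levels independently. Overlaps of calls were set against 20 such simulations with no change, where as many probes with the smallest p were taken in each direction as had been called, a test chosen after the overlaps were seen. Versions were R 4.3.3, limma 3.58.1, statmod 1.5.0, python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.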

Results

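Gene expression was measured in roots of a pair of rice lines on 6 oligonucleotide arrays of 2 colours. Nipponbare is a japonica cultivar, and 6-4 is a near-isogenic line that carries chromosome inserts of the indica cultivar Kasalath in that background. Plants grew in 12 L pots of a volcanic soil, either with phosphorus (P) supplied or without it, and 1.6 g of root was taken for RNA. Each array held both lines from the same condition, so that 3 arrays measured the control condition and 3 the P-deficient condition. The series describes 3 biological replicates of each line in each condition. The line in Cy5 was 6-4 on control replicate 2 and on P-deficient replicates 1 and 3, and Nipponbare on the other arrays. Each array carried 21495 rice probes, each named by a full-length cDNA accession, of which 20531 passed the filter on dim probes. The median spot was 3.25 to 6.94 times its local background in Cy3 and 7.32 to 9.83 times in Cy5, and the number of arrays limits the precision of every value below. The highest Cy3 values, 6.94 and 6.32, came from control replicate 2 and P-deficient replicate 2. Negative control spots there were 5.06 and 4.8 times their local background in Cy3, so these values overstate the signal of the probes. A log2 ratio is 6-4 over Nipponbare throughout, so a negative value means a lower signal in 6-4, which can reflect the level of a transcript or the binding of its Kasalath form. Several accessions can belong to 1 gene, and the gene descriptions are those of the array design.

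Averaged over both conditions, probes of a few resistance genes gave a far lower signal in roots of 6-4 than in roots of Nipponbare. A pair of probes for J78, an NBS-LRR protein of the class of intracellular immune receptors, had log2 ratios of -2.20 (AK102485, SE 0.14) and -1.95 (AK102672, SE 0.15). The NBS-LRR probe YR14 (AK065947) was at -1.88 (SE 0.16). Probes of 2 phosphate transporters were also lower in 6-4, with log2 ratios of -0.70 (SE 0.08) for high affinity phosphate transporter 2 (AK108907) and -0.45 (SE 0.06) for the transporter Pht1-2 (AK101170). Another probe with the description of AK108907 showed no difference (AK070341, 0.008, SE 0.045, limma adjusted p = 0.946). The Pht1-2 probe was at -0.77 (SE 0.09) under control. It did not pass under P deficiency, at -0.12 (SE 0.09, limma adjusted p = 0.42). Among called probes with a descriptive name that went the same way on every array, the largest difference in each direction came from 2 probes named cor2. The array design gives both that name, an NADPH-dependent oxidoreductase. AK103772 was higher in 6-4 at 2.43 (SE 0.26) and AK109414 lower at -3.09 (SE 0.10). AK109414 was well above background in 5 of the 6 channels of 6-4 and in all 6 of Nipponbare. A wall-associated protein kinase (AK105147) was higher in 6-4 at 1.08 (SE 0.10).

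In limma's test of this mean, 54 probes were higher and 136 lower in 6-4 at an adjusted p under 0.05, of 20528 tested. Of these 190, 149 went the same way on every array, against 5.3% of all probes. Differences of at least 2-fold numbered 8 higher and 24 lower. Adjusted p was 0.00189 and 0.0067 for the J78 probes, 0.0189 and 0.038 for the phosphate transporters, 0.0184 and 9.84e-05 for the cor2 probes, and 0.00965 for the kinase. Other probes lower in 6-4 were those of a cyclophilin, a protein-folding enzyme (AK058898, -1.95, SE 0.07), the product named csAtPR5 (AK059260, -1.80, SE 0.08) and the DNA replication protein RPA70a (AK064837, -1.38, SE 0.17). A cytochrome P450 (AK067458, -1.20, SE 0.12), a Bowman-Birk trypsin inhibitor (AK064050, -1.08, SE 0.14) and a probe described only as a sequence (AK105692, -0.90, SE 0.08) were lower too. Higher in 6-4 were the peroxidase prx12 (AK106200, 0.77, SE 0.09), the dehydration-responsive protein RD22 (AK105947, 0.75, SE 0.09), a prefoldin (AK067874, 0.70, SE 0.06) and cellulose synthase celA1 (AK100475, 0.67, SE 0.09). So were arginine decarboxylase of polyamine synthesis (AK058573, 0.65, SE 0.08; adjusted p = 0.0965 with the replicate block), a shikimate-pathway enzyme (AK058923, 0.64, SE 0.06), the LIM factor lim1 (AK058220, 0.60, SE 0.09) and a catalase (AK099923, 0.56, SE 0.08). Among 107 probes of NBS-LRR disease resistance genes 4 fell in 6-4 and none rose, 5 and 1 when adjusted over the list alone, and the list as a whole did not pass limma's camera (adjusted p = 0.258).

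**Figure D1:**
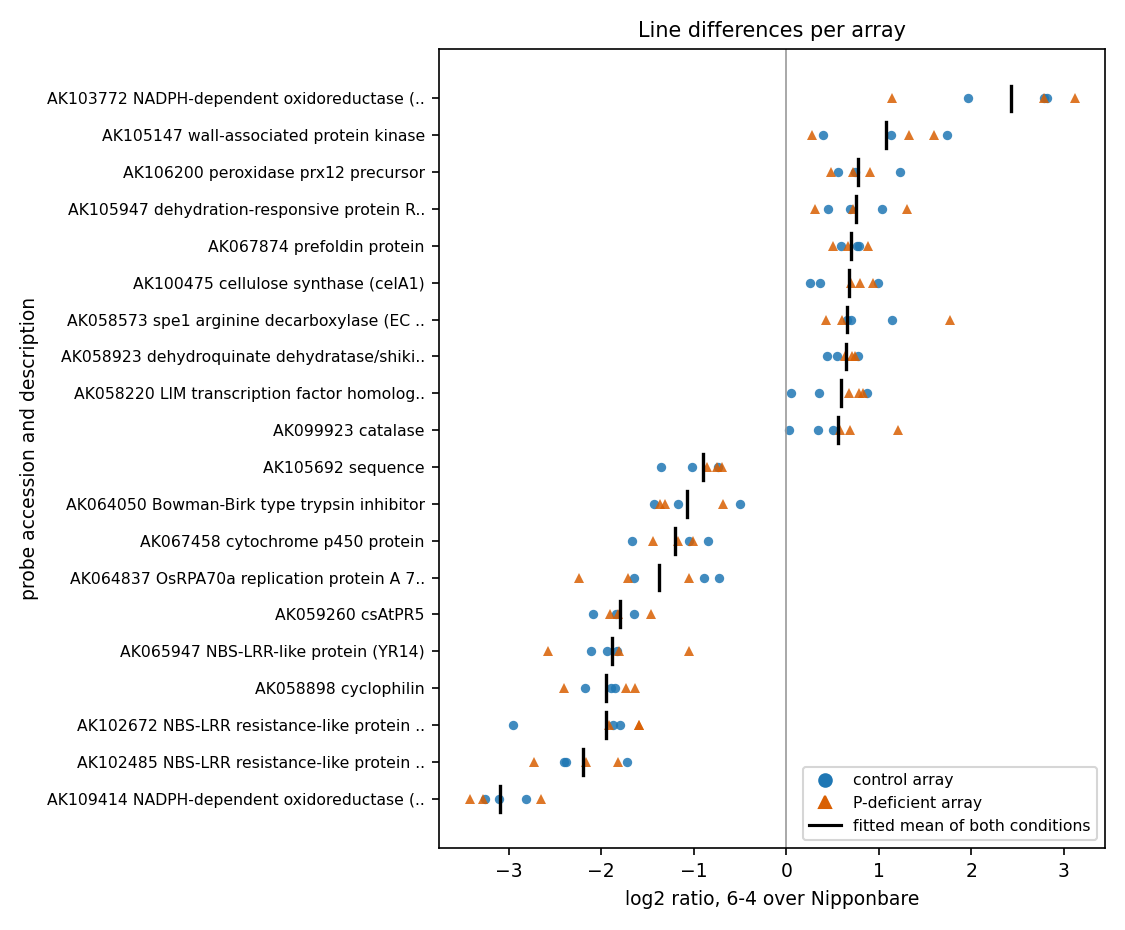
Log2 ratio of 6-4 over Nipponbare on each array (horizontal axis) for the 20 named probes with the largest mean line difference (vertical axis), with circles for the 3 control arrays, triangles for the 3 P-deficient arrays and a bar at the fitted mean of both conditions. All arrays of a probe lie on the same side of 0, from a mean of -3.09 for the cor2 probe AK109414 to 2.43 for the cor2 probe AK103772.

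Groups linked to P nutrition were lower in 6-4 as sets in the mean of both conditions. By camera, 2 lists passed under control, diterpenoid synthesis and low oxygen, and 0 under P deficiency. Of 10 phosphate transport probes 2 fell and none rose (6 fell when adjusted over the list alone), with a median log2 ratio of -0.37 (camera adjusted p = 0.000231, and adjusted p = 0.532 with an estimated correlation). Purple acid phosphatases release phosphate from organic compounds, and 2 fell (AK073222, PAP22, -0.51, SE 0.05; AK110804, -0.74, SE 0.07). These were 2 of 19 acid phosphatase and RNase probes, whose median was only -0.02, and 4 fell when adjusted over the list alone (camera adjusted p = 0.0394, and adjusted p = 0.445 with an estimated correlation). Of 5 membrane lipid remodelling probes the galactolipid-synthesis enzyme MGDG synthase fell (AK064148, -0.47, SE 0.07), and 3 fell when adjusted over the list alone (camera adjusted p = 0.0394, and adjusted p = 0.532 with an estimated correlation). MGDG synthase was at -0.88 (SE 0.105) under control and did not pass under P deficiency, at -0.05 (SE 0.105, limma adjusted p = 0.775). The list of diterpenoid synthesis was lower with a median of -0.48, 1 of 6 probes fallen and 5 when adjusted over the list alone (camera adjusted p = 0.000231, and adjusted p = 0.445 with an estimated correlation). Its fallen member was kaurene synthase (AK108710, -0.53, SE 0.07), and kaurene synthase and kaurene oxidase are also steps of gibberellin synthesis. The low oxygen list was lower with a median of -0.16, where 1 of 22 probes fell, alcohol dehydrogenase 2 (AK102799, -0.53, SE 0.05), and 4 when adjusted over the list alone (camera adjusted p = 0.000442, and adjusted p = 0.445 with an estimated correlation).

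Among the remaining sets lower in 6-4, none of 28 WRKY transcription factors passed, also when adjusted over the list alone, at a median of -0.10 (camera adjusted p = 0.00364, and adjusted p = 0.445 with an estimated correlation). Of 53 heat shock protein probes 1 fell, heat shock protein 80 (AK102426, -0.34, SE 0.05; adjusted p = 0.0857 with the replicate block), and 3 when adjusted over the list alone (camera adjusted p = 0.0394, and adjusted p = 0.532 with an estimated correlation). None of 7 metallothionein probes passed, also when adjusted over the list alone, at a median of -0.21 (camera adjusted p = 0.0394, and adjusted p = 0.532 with an estimated correlation). Sets higher in 6-4 were the cytosolic ribosomal proteins, at a median of 0.15 with 0 of 28 probes past the threshold in limma or when adjusted over the list alone (camera adjusted p = 0.000442, and adjusted p = 0.647 with an estimated correlation). Cellulose and wall synthesis was higher with 1 of 19 probes risen, celA1, and 3 when adjusted over the list alone (camera adjusted p = 0.00681, and adjusted p = 0.445 with an estimated correlation). The 6 aquaporins had a median of 0.12, with none risen and 1 when adjusted over the list alone (camera adjusted p = 0.0415, and adjusted p = 0.445 with an estimated correlation). The 45 sucrose and starch probes had a median of 0.04, with none risen, also when adjusted over the list alone (camera adjusted p = 0.0415, and adjusted p = 0.532 with an estimated correlation).

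With the scanner software version as a batch 398 probes passed, and within the 4 arrays read with version 7.1 the count was 233. Of the 20 largest named differences, 20 and 18 passed. All kept their direction in both, which follows from naming only probes that went the same way on every array. The fit within version 7.1 takes all its coefficients from 4 arrays, so little is left to estimate the spread. Among these arrays are control replicate 2 and P-deficient replicate 2, whose negative control spots were bright in Cy3. Past the threshold with the batch were 6 of the 12 lists: phosphate transport, cellulose, diterpenoid, WRKY, ribosomal and low oxygen, with medians of -0.37, 0.13, -0.48, -0.10, 0.15 and -0.16. The batch is balanced over conditions and dye orders, so it cannot move these medians. Within version 7.1 6 of the 12 passed (phosphate transport at -0.34, diterpenoid at -0.42, heat shock at -0.06, ribosomal at 0.12, sucrose and starch at 0.04, low oxygen at -0.19). The 6 lists not called within version 7.1 had medians there of -0.03 for acid phosphatase, -0.20 for membrane lipids, 0.11 for aquaporins, 0.14 for cellulose, -0.07 for WRKY and -0.09 for metallothioneins. The count of 190 fell to 35 without control replicate 2, 23 without P-deficient replicate 1, 34 without P-deficient replicate 2 and 21 without P-deficient replicate 3, and was 840 without control replicate 3.

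Roots grown without P raised transcripts of phosphate uptake, phosphate release and membrane lipid exchange relative to control roots, in the mean of both lines. MGDG synthase (AK064148) rose by 2.51 on the log2 scale (SE 0.20) and a purple acid phosphatase (AK110804) by 2.44 (SE 0.16). Phosphate transporters rose by 1.84 (AK109109, SE 0.27), 1.35 (AK101380, Pht1-2, SE 0.17) and 1.24 (AK101170, Pht1-2, SE 0.17). Flavanone-3-hydroxylase of flavonoid synthesis (AK071218) rose by 2.26 (SE 0.23) and alanine aminotransferase (AK107237) by 2.23 (SE 0.21). Transcripts of nitrate use went both ways: nitrate reductase was lowered by -1.64 (AK102178, SE 0.25) and -1.58 (AK102363, SE 0.28), and a nitrate transporter by -1.57 (AK068409, SE 0.25), while the transporter Nrt2 (AK072215), singled out after its values were seen, rose by 1.91 (SE 0.30). The iron transporter OsIRT1 (AK107681) was lowered by -1.71 (SE 0.33) and RD22 (AK105947) by -2.42 (SE 0.30).

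Limma called 213 probes raised and 96 lowered of 20530. The 3 P-deficient arrays did not overlap the 3 control arrays at any of these 309, against 16.5% of all probes and 10% by chance for 3 against 3. Adjusted p was 0.00118 for MGDG synthase, 0.000377 for the acid phosphatase, 0.0132, 0.00652 and 0.0106 for the transporters, 0.0166, 0.0324, 0.019 and 0.0196 for nitrate use, 0.0431 for OsIRT1 and 0.00642 for RD22. Other raised transcripts encoded a fatty acid CoA ligase (AK106436, 2.66, SE 0.38), a lectin (AK103206, 2.53, SE 0.13), and the chaperone HSP101 (AK105433, 2.12, SE 0.16). An AP2 domain factor (AK109606, 2.05, SE 0.29), an IAA-amino acid hydrolase (AK110647, 2.04, SE 0.35) and a cytochrome P450 (AK072715, 2.04, SE 0.19) rose as well. Other lowered transcripts encoded the root protein RCc2 (AK062911, -1.84, SE 0.17), a peroxidase (AK108824, -1.80, SE 0.18), germin-like proteins 2 and 1 (AK059781, -1.79, SE 0.16; AK059338, -1.59, SE 0.28) and a Cf-9 precursor (AK065680, -1.77, SE 0.22). Of 36 probes of nitrogen uptake and assimilation 2 rose and 3 fell, and 4 and 3 when adjusted over the list alone (camera adjusted p = 0.877).

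**Figure D2:**
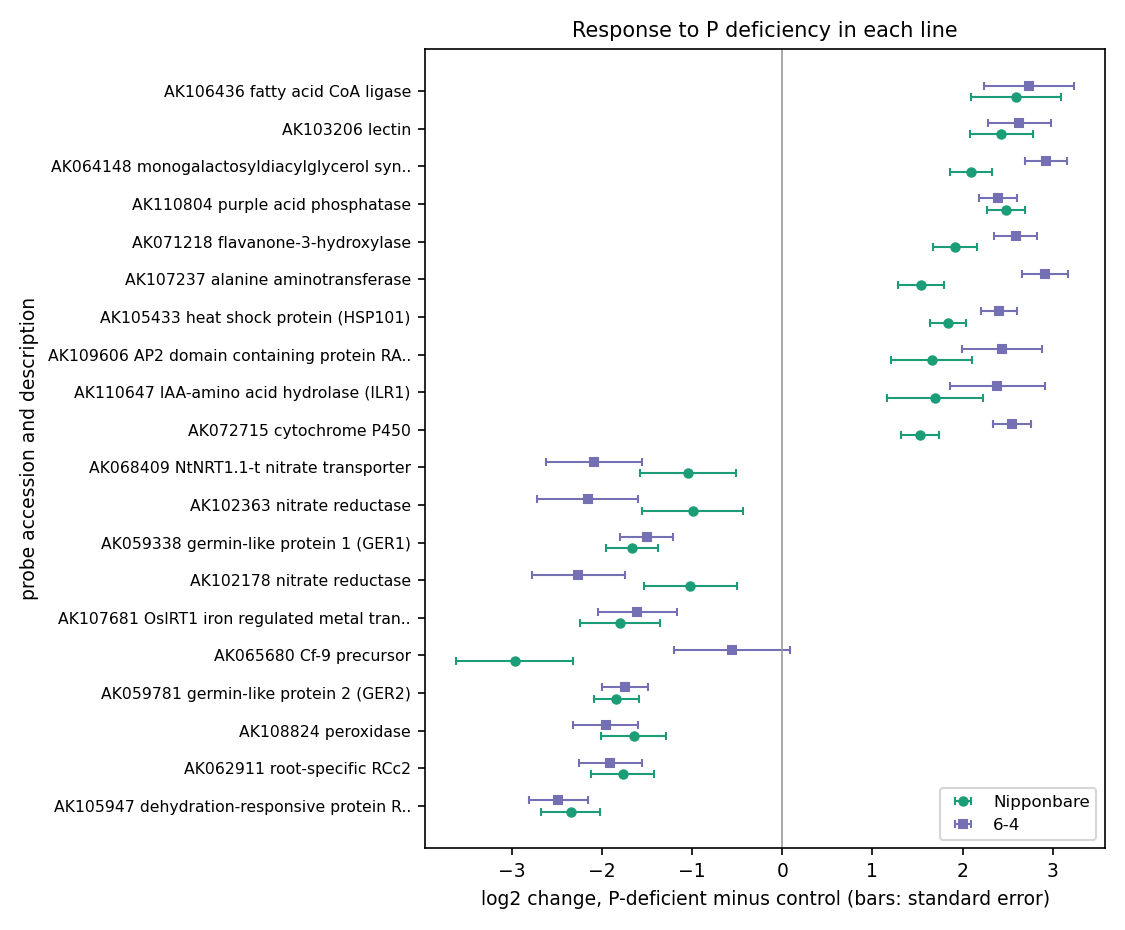
Log2 change from control to P-deficient roots (horizontal axis, with SE bars) in Nipponbare (circles) and 6-4 (squares) for the 20 named probes with the largest mean response (vertical axis). Both lines lie on the same side of 0 for each probe, for example 2.10 in Nipponbare and 2.93 in 6-4 for MGDG synthase (AK064148).

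As sets, phosphate transport rose with 3 of 10 probes called, 5 when adjusted over the list alone, and a median of 0.70 (camera adjusted p = 4.11e-05, and adjusted p = 0.314 with an estimated correlation). Acid phosphatase and RNase rose with 4 of 19 probes called, 5 when adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.401 with an estimated correlation). The called members were purple acid phosphatases between 1.10 (AK070684) and 2.44 (AK110804). Membrane lipid remodelling rose with 2 of 5 probes called, MGDG synthase and a glycerophosphodiester phosphodiesterase (AK071836, 1.04, SE 0.17), and 3 when adjusted over the list alone (camera adjusted p = 0.000362, and adjusted p = 0.314 with an estimated correlation). Diterpenoid synthesis rose with 2 of 6 probes called, also when adjusted over the list alone (camera adjusted p = 0.000147, and adjusted p = 0.407 with an estimated correlation). Those 2 were kaurene synthase A (AK100333, 1.72, SE 0.19) and kaurene oxidase (AK066285, 1.18, SE 0.18). Among heat shock proteins rose HSP101, an HSP70 (AK071518, 0.95, SE 0.13) and a further probe (AK101824, 1.04, SE 0.15). These were 3 of 53 probes, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0282, and adjusted p = 0.314 with an estimated correlation). Cellulose and wall synthesis fell as a set at a median of -0.26 with no member called, also when adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.407 with an estimated correlation). Its largest values were -0.67 for celA1 (AK100475, adjusted p = 0.25) and -0.62 for CesA-9 (AK072356, adjusted p = 0.209).

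With the replicate number as a block, 869 probes passed, and the lists of iron acquisition (median -0.23, adjusted p = 0.0485) and metallothioneins (median 0.20, adjusted p = 0.0485) passed too. These 2 values are camera at the preset correlation, where neither list passed without the block. Camera with an estimated correlation, a different test, gave adjusted p = 0.408 and adjusted p = 0.545 without the block. With the software version as a batch 748 probes and the same 6 lists passed, at the same medians, which the balanced batch cannot move. Within version 7.1 the counts were 226 probes and 4 lists, at medians of 0.58 for phosphate transport, 0.19 for acid phosphatase, 0.70 for membrane lipids and 0.90 for diterpenoid synthesis. Cellulose (-0.15) and heat shock proteins (0.07) did not pass there. The count of 309 fell to 90 without control replicate 1, 95 without control replicate 2, 201 without control replicate 3, 149 without P-deficient replicate 1 and 153 without P-deficient replicate 2, and to 15 with the arrays of replicates 1 and 3 alone.

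Within each line a phosphate transporter, MGDG synthase and a purple acid phosphatase rose. In Nipponbare a purple acid phosphatase (AK110804) rose by 2.48 (SE 0.21), chalcone synthase of flavonoid synthesis (AK061132) by 2.35 (SE 0.35), MGDG synthase (AK064148) by 2.10 (SE 0.23) and a phosphate transporter (AK109109) by 1.85 (SE 0.27). In 6-4 MGDG synthase rose by 2.93 (SE 0.23), the acid phosphatase AK110804 by 2.39 (SE 0.21), alanine aminotransferase (AK107237) by 2.91 (SE 0.26), the high affinity nitrate transporter Nrt2 (AK072215) by 2.48 (SE 0.39) and the phosphate transporter AK109109 by 1.84 (SE 0.27). RD22 (AK105947) fell by 2.35 in Nipponbare (SE 0.33) and by 2.49 in 6-4 (SE 0.33), and germin-like protein 2 (AK059781) fell by 1.84 and 1.75 (SE 0.25 in both).

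Limma's single-channel fit called 120 probes raised and 52 lowered in Nipponbare and 217 raised and 60 lowered in 6-4, of 20054 tested in each line. Adjusted p in Nipponbare was 0.000477, 0.0082, 0.00237 and 0.00739 for the 4 transcripts named first, and in 6-4 it was 0.000103, 0.000139, 0.000139, 0.00665 and 0.00458 in the order given. Other large responses in Nipponbare were those of a fatty acid CoA ligase (AK106436, 2.59), a lectin (AK103206, 2.43), an amino acid channel (AK101693, 1.87) and nuclease I (AK059608, 1.71) upward. Downward in Nipponbare went the pair of hsr203J probes (AK061124, -1.70; AK059449, -1.39) and an anionic peroxidase (AK104936, -1.55). Other large responses in 6-4 were those of a P-glycoprotein (AK107554, 2.56), a cytochrome P450 (AK072715, 2.55), an ABC transporter (AK067653, 2.54) and the protein CPRD12 (AK110700, 2.49) upward. Downward in 6-4 went a peroxidase (AK108824, -1.96), RCc2 (AK062911, -1.91) and a protein phosphatase of type 2C (AK068836, -1.21). Raised in both lines were 88 probes, where independent lists of these sizes would share 1.3, and lowered in both were 18, against 0.16. Both lists come from the same arrays, and lists of these lengths from simulated arrays with no difference shared 89.4 upward on average (at most 100 in 20 draws) and 35.35 downward (at most 39). The shared arrays alone could thus give overlaps as large as these.

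In Nipponbare phosphate transport rose as a set with 1 of 10 probes called and 6 when adjusted over the list alone (camera adjusted p = 0.000294), acid phosphatase and RNase with 3 of 19 and 4 (0.000303), and membrane lipid remodelling with 1 of 5 and 3 (0.000303). Cellulose and wall synthesis fell there as a set at a median of -0.37 with no member called, also when adjusted over the list alone (camera adjusted p = 0.00916). In 6-4 phosphate transport rose with 3 of 10 probes called and 5 when adjusted over the list alone (camera adjusted p = 6.12e-06), acid phosphatase and RNase with 4 of 19 and 6, where 2 also fell when adjusted over the list alone (2.96e-06), and membrane lipid remodelling with 2 of 5 and 3 (7.52e-08). Diterpenoid synthesis rose in 6-4 with 2 of 6 probes called and 2 when adjusted over the list alone (camera adjusted p = 0.000527), and its median in Nipponbare was 0.52 (camera adjusted p = 0.189). The difference between the lines' responses did not pass for any list, as given below for the line effect. An estimated correlation is not used here for the single-channel fit. OsPT1 (AK063990) had 0.91 in Nipponbare and 1.27 in 6-4 and did not pass in either line (adjusted p = 0.175 and 0.0581), and with the replicate block it did (0.0206 and 0.00434).

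The replicate block raised the counts to 1304 raised and 1117 lowered in Nipponbare (53.9% raised against 69.8%) and 1496 and 1462 in 6-4 (50.6% against 78.3%). Among the brightest probes with the block 352 were raised and 234 lowered in Nipponbare and 408 and 239 in 6-4. The software version as a batch gave 547 and 327 in Nipponbare and 637 and 392 in 6-4. Within version 7.1 limma called 0 probes in Nipponbare (1056 at an unadjusted p under 0.05) and 2 in 6-4. None of the 20 largest named responses of each line was called there. All kept their direction, which the rule of no overlap between conditions left little room to change. The called lists all passed there, at medians of 0.59, 0.04, 0.61 and -0.32 for phosphate transport, acid phosphatase, membrane lipids and cellulose in Nipponbare. In 6-4 their medians were 0.59, 0.28, 0.79 and 1.26 for phosphate transport, acid phosphatase, membrane lipids and diterpenoid synthesis. With the batch these lists passed at the medians of the fit without it, which the balanced batch cannot move. Leaving out control replicates 1, 2 or 3 gave 26, 14 and 87 calls in Nipponbare, and leaving out P-deficient replicates 1, 2 or 3 gave 25, 37 and 43. In 6-4 the counts were 72 and 70 without control replicates 1 and 2 and 108, 106 and 120 without P-deficient replicates 1, 2 and 3.

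Under control conditions, with P supplied, several transporter probes were lower in 6-4 than in Nipponbare. Those of phosphate transporters had log2 ratios of -1.42 (SE 0.27) for high affinity phosphate transporter 11 (AK062362), -0.77 (SE 0.09) for Pht1-2 (AK101170), -0.72 (SE 0.14) for OsPT1 (AK063990) and -0.60 (SE 0.11) for high affinity phosphate transporter 2 (AK108907). The nitrate transporter Nrt2 (AK072215) was at -1.40 (SE 0.18). Another probe described as high affinity phosphate transporter 2 (AK070341) did not pass, at 0.16 (SE 0.066, limma adjusted p = 0.158). Kaurene synthase A (AK100333) was at -1.04 (SE 0.19) and kaurene oxidase (AK066285) at -0.94 (SE 0.16). The NBS-LRR probes J78 (AK102485 at -2.20, SE 0.20; AK102672 at -2.18, SE 0.22) and YR14 (AK065947 at -2.04, SE 0.23) were lower as in the mean. Higher in 6-4 were the cytochrome P450 CYP87A3 (AK065302 at 1.33, SE 0.25; AK060292 at 1.32, SE 0.27) and a xyloglucan endotransglycosylase of wall loosening (AK070734 at 1.20, SE 0.22).

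Adjusted p in limma was 0.0257, 0.0152, 0.0287, 0.0259 and 0.0155 for the transporters in the order given, 0.0258 and 0.0223 for the kaurene enzymes, 0.0114, 0.0145 and 0.0151 for J78 and YR14, and 0.0259, 0.0307 and 0.0245 for the probes higher in 6-4. Further probes were higher in 6-4 for an oxophytodienoic acid reductase of jasmonate synthesis (AK105590, 1.95, well above background in 2 of the 3 Nipponbare channels) and a flavin-containing monooxygenase (AK071801, 0.98), and lower for a Cf-9 precursor (AK065680, -1.97) and the NBS-LRR probe YR5 (AK073424, -1.55, well above background in 2 of the 3 channels of 6-4). Diterpenoid synthesis was lower as a set with 3 of 6 probes fallen, 4 when adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.793 with an estimated correlation), and its median was -0.73, -0.84 with the batch and -0.85 within version 7.1. Low oxygen was lower with 4 of 22 fallen, alcohol dehydrogenases and a pyruvate decarboxylase, and 5 fallen and 1 risen when adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.793 with an estimated correlation), and its median was -0.23, -0.22 with the batch and -0.25 within version 7.1. Of those 4, only alcohol dehydrogenase 2 (AK102799) was also called lower under P deficiency, at -0.45. Pyruvate decarboxylase pdc3 (AK100433) and alcohol dehydrogenase 1 (AK073964), both outside the brightest probes, were called higher there, at 0.75 and 0.45. The remaining one, Adh2-N (AK101288), was at 0.23 there and did not pass. Phosphate transport, with 5 of 10 fallen (7 fallen and 1 risen when adjusted over the list alone) and a median of -0.45, did not pass as a set (camera adjusted p = 0.0503), and did with the batch at -0.39 (0.0308) and with the replicate block (0.0099). Without either it had adjusted p = 0.804 with an estimated correlation.

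In all 1383 probes were called higher and 1270 lower in 6-4 under control, of 20528, but dim spots supplied most of these. Of the 2653, 297 lay among the 6844 brightest probes, where limma called 31 when these were tested alone, all lower. Negative control spots on control replicate 2 were 5.06 times their local background in Cy3 and 1.09 times in Cy5, against 2.86 and 1.45 in Cy3 on control replicates 1 and 3. Within version 7.1 the count was 2792 and with the software version as a batch 1791. The direction turned on the scaling: 103 were higher and 724 lower with median centring, and 464 and 240 with the scanner software's processed signals. The count was 2 with the control arrays alone, 2 without control replicate 2, 1602 without control replicate 1, 4241 without control replicate 3, 306 without P-deficient replicate 1 and 25 without P-deficient replicate 3.

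Under P deficiency the probes of J78 and YR14 were lower in 6-4, and 2 xyloglucan enzymes were higher. J78 (AK102485) was at -2.20 (SE 0.20), YR14 (AK065947) at -1.73 (SE 0.23) and RPA70a (AK064837) at -1.72 (SE 0.25). Higher in 6-4 were an endo-xyloglucan transferase (AK061093, 1.49, SE 0.22) and the xyloglucan endotransglycosylase-like XEB (AK058291, 1.32, SE 0.29), which act on wall xyloglucan. High affinity phosphate transporter 2 (AK108907) was lower at -0.80 (SE 0.11). Another probe of that description (AK070341) did not pass, at -0.14 (SE 0.066, limma adjusted p = 0.197).

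Adjusted p in limma was 0.0111, 0.019 and 0.0219 for J78, YR14 and RPA70a, 0.0219 and 0.0435 for the wall enzymes, and 0.0211 for the phosphate transporter probe AK108907. Also higher were a thionin (AK062831, 1.82), an anionic peroxidase (AK104936, 1.49), an endopolygalacturonase (AK103106, 1.07), a rab geranylgeranyl transferase (AK102430, 1.10) and the origin recognition protein OsORC1 (AK103068, 1.09). The endopolygalacturonase, a dim probe, was at 1.99 on replicate 2 and at 0.16 and 0.19 on replicates 1 and 3. The rab geranylgeranyl transferase, also dim, and OsORC1 had the opposite sign under control, at -0.69 (SE 0.08) and -0.53 (SE 0.18). None of the 30 lists tested passed camera in this condition (4 at an unadjusted p under 0.05). The list nearest to the threshold was the ribosomal proteins at a median of 0.18 (adjusted p = 0.0514). With the software version as a batch 3 lists passed and within version 7.1 2 did. The probe calls numbered 886 higher and 949 lower, of which 187 lay among the brightest probes. Tested alone, the brightest probes gave 4 calls in limma, all lower, so no probe named here as higher passed among them. Negative control spots on P-deficient replicate 2 were 4.8 times their local background in Cy3, against 1.19 and 1.37 on replicates 1 and 3. The count of 1835 was 2354 with the batch, 2193 within version 7.1, 10 with the P-deficient arrays alone, 470 and 4477 without control replicates 2 and 3, and 9, 9 and 6 without P-deficient replicates 1, 2 and 3.

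Testing whether the line difference itself depended on the condition, which is also whether the lines responded to P deficiency by different amounts, gave the following among bright spots. The difference, P-deficient minus control, was 1.37 (SE 0.18) for alanine aminotransferase (AK107237), 1.27 (SE 0.14) for CPRD12 (AK110700), 1.22 (SE 0.28) for kaurene synthase A (AK100333) and 0.65 (SE 0.13) for Pht1-2 (AK101170), so that these rose more in 6-4. Other probes of the same descriptions did not pass. Kaurene synthase A probe AK100631 was at 0.09 (SE 0.275, limma adjusted p = 0.857) and Pht1-2 probe AK101380 at 0.43 (SE 0.26, limma adjusted p = 0.299). High affinity phosphate transporter 11 (AK062362) had a difference of 1.05 (SE 0.39) that did not pass (adjusted p = 0.108). Adjusted p in limma over all probes was 0.00681, 0.0054, 0.0287 and 0.0197 for the first 4, and none passed when the brightest probes were tested alone (0.21, 0.21, 0.325 and 0.317).

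Over all probes limma called 1927 differences above 0 and 2107 below, of 20528. The called share was 39.19% among the dimmest probes, 16.92% in the middle and 2.84% among the brightest, with the probes divided evenly by brightness. Tested alone, the brightest probes gave 0 calls in limma (781 at an unadjusted p under 0.05). Named probes had to show no overlap of the conditions' arrays, which set aside such dim probes as a rab geranylgeranyl transferase (AK102430, 1.79) and an oxophytodienoic acid reductase (AK105590, -1.84). Among those left, the largest differences above 0 outside the brightest probes belonged to a Cf-9 precursor (AK065680, 2.41) and a selenium-binding protein (AK111304, 1.56). Germin-like protein 2 (AK059812, 1.53, against 0.10 for AK059781 of that name) and an FRO2-like NADPH oxidase (AK067009, 1.41) followed. An anionic peroxidase (AK104936, 1.35) and wall-associated kinase 2 (AK111541, 1.32; AK071360, 1.23) came next. Those below 0 belonged to ECA1 (AK062599, -1.33), peroxidase Prx3 (AK061040, -1.29), phytoene synthase (AK108154, -1.24), SKIP2 (AK071138, -1.22) and a Kelch-like protein (AK066661, -1.18). A zinc finger protein (AK108320, -1.16), an actin (AK109896, -1.14), an ABC transporter (AK069041, -1.14), a bHLH factor (AK100208, -1.12) and alpha expansin 26 (AK071328, -1.06) came next below 0. Of the 30 lists none passed camera (0 at an unadjusted p under 0.05). The count of 4034 was 3292 with the software version as a batch, 4750 within version 7.1, 0 without control replicate 2 in limma (4100 at an unadjusted p under 0.05), 6149 without control replicate 3, and 1624, 989 and 1381 without P-deficient replicates 1, 2 and 3.

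**Figure D3:**
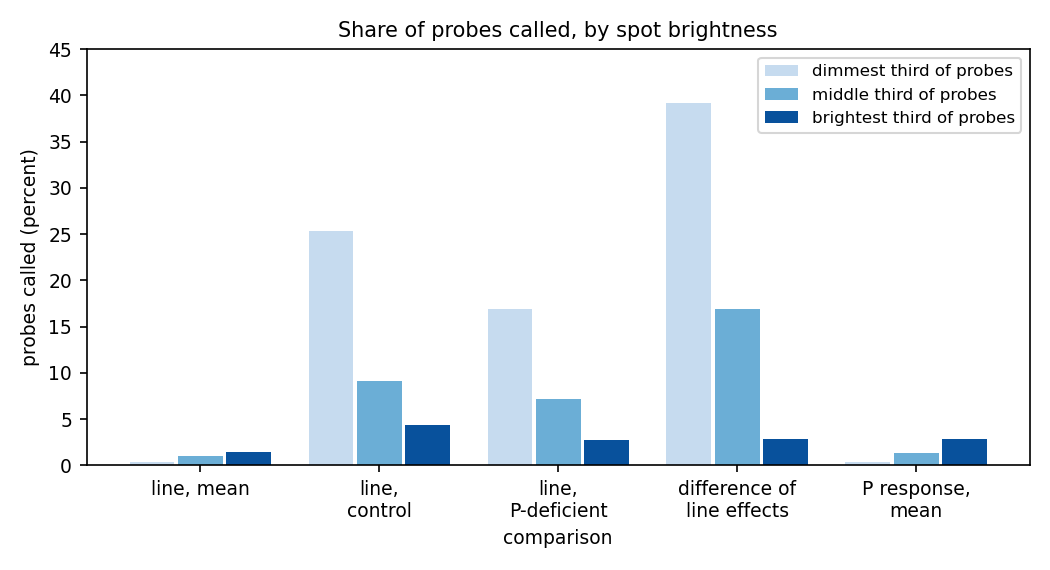
Percent of probes with an adjusted p under 0.05 (vertical axis) in 5 comparisons (horizontal axis), with bars for the dimmest, middle and brightest probes by mean spot intensity. The difference of the line effects was called at 39.19% of the dimmest and 2.84% of the brightest probes, and the mean response to P deficiency at 0.32% and 2.86%.

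Bright probes raised by P deficiency were lower in 6-4 than in Nipponbare while P was supplied, a set chosen after the data were seen and on the same arrays. The 141 called probes among the brightest had median log2 ratios of -0.51, -0.48 and -0.52 on the 3 control arrays and of -0.12, -0.12 and -0.07 on the 3 P-deficient arrays. Under control 134 of the 141 were lower in 6-4 by the fit, 111 of them on every control array. Their median response was 1.06 in Nipponbare and 1.35 in 6-4. Among 10000 random lists of as many bright probes, the median under control ranged from -0.06 to 0.06, against -0.47 for the set, and the median difference between conditions from -0.05 to 0.08, against 0.41. Such lists do not share the set's correlation, and camera with an estimated correlation gave p = 0.00165 under control and p = 0.00491 for the difference. The 72 raised probes outside the brightest had smaller medians, -0.29 under control and 0.15 for the difference, which was above 0 for 47 of them. Called lower in 6-4 in the mean of both conditions were 30 of the probes raised by P deficiency, where independent lists would share 1.41. Lists of these lengths from simulated arrays with no difference shared 1.9 on average and at most 4 in 20 draws. The simulation drew ratios and levels independently, so it cannot show what shared arrays add here. Part or all of the excess may come from the shared arrays. Those 30 came from 136 and 213 calls.

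**Figure D4:**
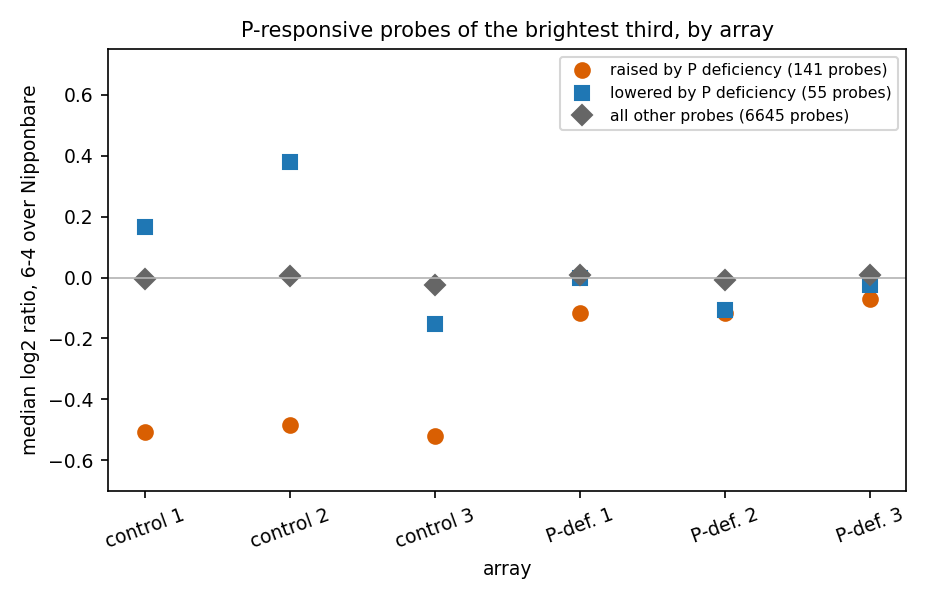
Median log2 ratio of 6-4 over Nipponbare (vertical axis) on each of the 6 arrays (horizontal axis) for the brightest probes raised by P deficiency (141, circles), lowered by it (55, squares) and not called (6645, diamonds). The raised probes lie between -0.52 and -0.48 on the control arrays and between -0.12 and -0.07 on the P-deficient arrays.

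Other lists did not pass camera in any of the 7 comparisons over all arrays and probes without the replicate block. Exceptions under other settings were pathogenesis-related proteins in the mean line effect, with the block (median -0.02, adjusted p = 0.00317, and without it adjusted p = 0.647 with an estimated correlation) and within version 7.1, NBS-LRR genes in the mean line effect among the brightest probes (adjusted p = 0.744 with an estimated correlation over all probes), and iron acquisition with the block, as given above. The lists were glycolytic bypass and organic acids, nitrogen, iron and sulfur uptake and assimilation, wall loosening, phenylpropanoid and lignin, class III peroxidases, glutathione transferases, antioxidant enzymes, pathogenesis-related proteins, photosynthesis as a marker of green tissue, histones and cell division, ethylene, auxin, jasmonate, NBS-LRR disease resistance, transposon-related genes, and late embryogenesis proteins and dehydrins. In the phosphate sensing list, too small for a set test, the 2 probes of phosphate-induced protein 1 did not pass in any comparison, with mean line ratios of 0.29 (AK070419, adjusted p = 0.0981) and -0.01 (AK099621, adjusted p = 0.938).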

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

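The tests of Cy3 brightness and of the lines' response in this part were chosen after their results were seen, while the test of the difference between conditions was planned. The correlation between arrays was first taken before loess, where it was 0.83, 0.836 and 0.52 for replicates 1, 2 and 3 outside the brightest probes and 0.098, 0.481 and 0 among them. That version did not single out replicate 2 and left the brightest probes undecided, and the version after loess replaced it once both had been seen. The test of the lines' response was at first the count of differences among the brightest probes tested alone (0 in limma, 781 at an unadjusted p under 0.05). It was replaced by the median on replicates 1 and 3.

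The line effect depended on the condition at 4034 probes in limma's test of the difference itself, and most of these were dim. The ratios of Cy5 over Cy3 on control replicate 2 and P-deficient replicate 2, where 6-4 is in opposite dyes, correlated at 0.729 outside the brightest probes, against 0.033 and -0.142 for replicates 1 and 3. Extra Cy3 signal on dim spots of these arrays may therefore account for the calls outside the brightest probes. Over all the brightest probes the correlation was 0.023, which argues against such signal across them as a whole. Only 2.84% of the brightest probes were called, so this correlation cannot show whether the called ones carry it. Called probes had a median difference of 0.081 on the arrays of replicates 1 and 3, turned to the called direction, against 1.25 on those of replicate 2 and 0.664 in the fit. By array, the turned medians were -0.659 on control replicate 2, 0.591 on P-deficient replicate 2 and -0.061 to 0.041 on the other arrays. Lines that respond differently to P supply would by that alone differ on replicates 1 and 3 too. These values argue against such a response alone. Joined to a dye effect of the same size on the same probes, it would give these values too and cannot be told apart from Cy3 signal.

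Among named genes, the difference between conditions was called for 14 bright probes; dimmer named genes were set aside because of the Cy3 signal, and none of the 14 passed when the brightest probes were tested alone. These were nitrate transporter Nrt2 (AK072215, 1.14), alanine aminotransferase (AK107237, 1.37), CPRD12 (AK110700, 1.27), kaurene synthase A (AK100333, 1.22), a P-glycoprotein (AK107554, 1.20), an ABC transporter (AK067653, 1.17) and a cytochrome P450 (AK072715, 1.02). Smaller differences were called for a peptidylprolyl isomerase (AK064825, 0.83), a subunit of initiation factor eIF2B (AK100837, 0.72), a purple acid phosphatase (AK071643, 0.70), flavanone-3-hydroxylase (AK071218, 0.67), Pht1-2 (AK101170, 0.65), a glycerophosphodiester phosphodiesterase (AK071836, 0.60) and hsr203J (AK059449, 0.59). All are on the log2 scale and above 0.

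Negative control spots, which are not used in the comparisons, gave signal in Cy3. Their median was 2.86 times the local background on control replicate 1, 5.06 on control replicate 2 and 4.8 on P-deficient replicate 2. On the other arrays it was 1.19 to 1.45, and in Cy5 it was 1.06 to 1.10 on all 6 arrays.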

How the results depend on the processing

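Chosen after the data had been seen were the tests on the brightest probes, on the arrays of software version 7.1 and on replicates 1 and 3, and lists with the batch. The cause of each change was not tested unless given. Without background subtraction the calls were 26 in the mean line effect, 2 under control, 1 under P deficiency and 0 for the difference in limma (3900 at an unadjusted p under 0.05). An offset of 16 gave 108 in the mean line effect. The scanner software's processed signals gave 19, 704, 185 and 1962, and 82, 77 and 167 in the mean response, Nipponbare and 6-4, and the series table gave 19, 718, 185 and 1986 for the line effects. Requiring all 12 channels well above background gave 1217 under control, 910 under P deficiency and 2343 for the difference. Median centring gave 64, 827, 40 and 2138 line effects, with 12.5% higher under control against 52.1% and 75.9% of the differences above 0 against 47.8%. The processed signals and the series table tilted the other way, with 30.4% and 30.6% of the differences above 0. Median scaling gave 136, 56 and 116 responses, 78.7% raised in the mean against 68.9%. Without a dye term each condition's estimate comes from its own arrays alone, while the spread comes from all 6. Limma then called 40, 24, 13 and 0 line effects (1785 at an unadjusted p under 0.05 for the last). With each condition's arrays alone for the spread too, it called 2 under control and 10 under P deficiency.

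The replicate block gave 308, 1355, 701 and 2549 line effects and 869, 2421 and 2958 responses. For line effects the block, like version 7.1 alone, leaves little to estimate the spread from. Software version as a batch gave 398 in the mean line effect and 748, 874 and 1029 responses. The brightest probes alone, fewer probes, gave 115, 31, 4 and 0 line effects, and with the block 113, 41 and 0 under control, under P deficiency and for the difference (372 at an unadjusted p under 0.05 for the last), and 857, 586 and 647 responses. On version 7.1, fewer arrays, the responses in limma were 0 in Nipponbare (1056 at an unadjusted p under 0.05) and 2 in 6-4. Replicates 1 and 3 gave 15 in the mean response, and the 6 Nipponbare channels fitted alone without a dye term 104.

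Leaving out 1 array gave 21 to 840, 2 to 4241, 6 to 4477 and 0 to 6149 line effects and 90 to 223, 14 to 87 and 70 to 214 responses, where the lone arrays' spread is assumed to equal that of the rest.

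The mean line effect had 12 lists. Camera with an estimated correlation called 0 (2 at an unadjusted p under 0.05), and fry 1 that is not among the 12 (antioxidant enzymes). The brightest probes gave 6 (5 of the 12), the batch 6 (each among the 12) and version 7.1 7 (6 of the 12). Without background subtraction 9 passed and without the filter 11, each among the 12. The block gave 12 (11 of the 12), with pathogenesis-related proteins in (adjusted p = 0.00317) and heat shock proteins out (0.0589). Under control, 2 lists became 0 with an estimated correlation (1), 5 without background subtraction, 3 without the filter (1 of the 2) and 4 with the batch. Under P deficiency, 0 lists (4 at an unadjusted p under 0.05) became 2 with the block, 2 without the filter, 3 without background subtraction, 3 on the brightest probes, 3 with the batch and 2 on version 7.1. For the difference, 1 list passed on the brightest probes and 1 on version 7.1. In the mean response, 6 lists became 0 with an estimated correlation (3) and 3 on the brightest probes.

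Of 5229 values of 152 named genes, 4083 kept direction and side of the threshold, 1045 lost the call, 93 gained it and 8 turned. The 8 were uncalled: AK099621 in the mean line effect (0.027 without control replicate 2, 0.004 without control replicate 3, 0.027 without P-deficient replicate 2, and from -0.045 without control replicate 1), in the mean response (-0.004 on version 7.1) and in Nipponbare (0.039 without background subtraction, 0.022 without control replicate 2, and from -0.17 without P-deficient replicate 2), and AK070419 for the difference (-0.007 with median centring, -0.023 without a dye term). Spots at 3.25 to 6.94 times background in Cy3 limit what dim probes can show. The test by chromosome position was not run, since no accession was found in the gene table.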

Other observations

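Written before the results were seen were the tests of the choice of probes, of compressed ratios and of other splits of the arrays; the other tests in this part were chosen after.

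Bright probes raised by P deficiency were lower in 6-4 while P was supplied, at a median of -0.47 over 141 probes against -0.12 under P deficiency, and less so for 72 raised probes outside the brightest (-0.29 and -0.15). A dye effect is argued against by a median of -0.483 on control replicate 2, the control array with the opposite dye order, and the choice of probes by a median of -0.379 over the 64 bright probes called raised in Nipponbare. Ratios compressed at high brightness would make the difference between conditions smaller for dimmer probes. Among the bright raised probes without a saturated spot it was 0.366 for the 68 dimmer and 0.427 for the 68 brighter. For the 72 raised probes outside the brightest it was 0.15. By the rule written beforehand, 0.366 for the 68 dimmer probes argues against compression among the bright probes. The comparison with the 72 probes was not part of that rule. The difference stayed above 0 but was smaller for dimmer probes, so compression is left open. Nipponbare roots may have been nearer to P starvation than 6-4 roots under control, but probes lowered by P deficiency had a median of 0.179 there and their arrays went both ways (0.165, 0.381 and -0.154). This cannot be told apart from a lower basal level of these transcripts in 6-4, since tissue P is not analysed here.

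Far lower levels in 6-4 were more frequent than far higher ones, with 24 against 8 probes at 2-fold or more (exact binomial p = 0.007, which takes probes as independent although J78 has 2). Among the brightest probes the counts were 9 lower and 5 higher. Probes of Nipponbare sequence may bind Kasalath alleles less well, which would lower a ratio in both conditions alike, and 19 of the 24 had a difference between conditions within 2 SE. For the 24 lower probes, among them J78 and YR14, weaker binding cannot be told apart from lower expression, because no Kasalath sequence was used here. For the 8 higher probes weaker binding would act the other way.

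Other splits of the arrays were counted for each comparison. In the mean line effect 2 of 30 splits gave at least 190 calls, so chance cannot be excluded by this count. The highest other split, with the sign turned on the P-deficient arrays, is the difference between conditions itself and gave 4034. Its cause, Cy3 signal or lines that respond differently joined to a dye effect, is left open here. Splits were too few for a share under 0.05 under control (1 of 4, with 2653 calls), under P deficiency (1 of 4, with 1835), for the difference (1 of 9, with 4034), in the mean response (1 of 10, with 309), in Nipponbare (1 of 9, with 172) and in 6-4 (1 of 9, with 277), and the highest other split gave 0 calls in limma in each of these 6.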
